A study of Solanum lycopersicum with 24 samples.

How the data were processed

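RNA from tomato fruit pericarp was measured on 24 one-colour Agilent arrays, 3 for each of 8 groups of labelled line (M82 or IL8-3) and stage. Per the labels' protocols, fruit was sampled from 8 plants, total RNA was extracted by the SDS-phenol method and purified with RNeasy columns, and targets were labelled with Cy3 using the Low Input Quick Amp kit. Per the file headers, the deposited scanner files were made by Agilent Feature Extraction 10.10.1.1, which subtracted the local background and gave a processed signal for each spot as a linear intensity, not normalized between arrays. The deposited series values are intensities too: each equals the processed signal of the same spot times one factor per array, from 3.01 to 4.36. The medians of the columns, replicates in order, were 161.1, 149.5 and 152.5 for M82 10 DAF, 137, 140.6 and 147.5 for M82 20 DAF, 163.9, 147.1 and 149.1 for M82 30 DAF, and 144.1, 152.7 and 137.2 for M82 ripening. They were 132.3, 132.4 and 143.8 for IL8-3 10 DAF, 127.1, 116.9 and 129.3 for IL8-3 20 DAF, 114.7, 127.3 and 125.7 for IL8-3 30 DAF, and 87.63, 97.79 and 91.53 for IL8-3 ripening. The scale of these values is therefore linear and not centred per gene, while the rule behind the factor stays unknown. They lack 160 non-control probes and were used as an alternative.

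The processed signals were put on a log2 scale, and the 75th percentile of each array's non-control probes was subtracted. The 70 spots that the software marked as nonuniform were left out, and so was 1 probe marked on every array of a group. Probes were tested when they were well above background on all 3 arrays of at least 1 group, which left 30260 of 43803 non-control probes; 21949 were well above background on all 24 arrays. Median intensity ranged from 23.6 to 52.5 and the 75th percentile from 417.1 to 650.2. The slope of the spike-in controls was 0.987 to 1.03 and 0 spots were saturated. Dim genes are the least precise, and the number of arrays limits precision.

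limma 3.58.1 in R 4.3.3 fitted one coefficient per group over all 24 arrays (16 residual and 1.84 prior degrees of freedom). Comparisons were the labelled lines at each stage, their mean, the successive stages within a labelled line, and the difference of these steps between lines. A probe was called at a Benjamini-Hochberg adjusted p under 0.05, and all counts of calls are probes. For genes with several probes, the probe with the highest mean stood for the gene, which gave 25134 genes; among 3772 genes with several tested probes, 6 to 24 per comparison had probes called in opposite directions. Where a probe was not well above background on any array of a group, its fold is given as a bound: the brighter group's mean against, per array, the higher of the lowest signal well above background and the probe's own. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 matched identifiers and drew the figures, and the data.table package, version 1.17.8, read the files.

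The files name genes by 34527 locus tags. The reference table, of assembly SLM_r2.1, held 0 of them, so no tag was given a gene name, and none of its coordinates was used. Probes with a locus tag numbered 42569 and those without 1234; 1071 of the latter were tested. Before the data were examined, 24 gene lists, the tests, the groups and the alternatives were fixed. In 8 of the lists, members had been written as locus tags, 45 in all, every one of them on the array and tested; this membership rests on general knowledge of tomato and could not be checked against a table. The other 16 lists, whose members could be found only by name or description, among them markers of other tissues, are not analysed here. Lists of at least 5 members were tested with limma's camera with a preset correlation of 0.01, adjusted over the 5 such lists of a comparison, and again with an estimated correlation. The other 3 lists are described by their members. Counts of members include loci that were well above background on only some arrays of a group, for which a call gives a direction and no reliable size. Counts of list members are over all probes tested; adjusted over the list alone they were equal except where given.

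The rule for single genes took those with a named function and the largest changes, up to 3 members per list and direction, a fixed set of names, and the 5 chromosome 8 genes with the largest mean line difference of the same sign, called at all 4 stages. Without names only the last part could be applied as written. It gave 2 genes that were higher and 3 that were lower, of which 2 per direction are printed; the list members are given as counts. The chromosome of a gene and the order along it were read from the locus tag, whose naming convention carries them; no table given places the tags, although the planned test asked for one. Shares of chromosomes were compared with two-sided Fisher's exact tests, adjusted over the 12 chromosomes. The label check was made after single loci had been looked at by gene names from general knowledge, which no table given supports and which are not used here. The 4 steps that share no arrays, the windows, the 2-fold counts and the fits within a slide were added after the data were seen.

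The file headers place the arrays on 6 slides of 4. Slides 1 to 3 held only arrays labelled M82 and slides 4 to 6 only arrays labelled IL8-3, with successive stages sharing a slide. Steps and interactions were therefore also fitted with the slide as a block and within the shared slide, where 4 of the 6 steps have a single array on one side, whose spread is not measured, and line comparisons with the slide as a random block (correlation of arrays on one slide -0.265). Other alternatives were quantile normalization, median centring, normexp background correction with an offset of 50, the deposited series values, other filters, only the groups compared, a variance trend with robust estimation, array weights, the replicate number as a block and leaving out each array. Replicate numbers were checked for pairing by the correlation of deviations from the group means; only for 20 against 10 DAF on the arrays labelled IL8-3 were all 3 same-number correlations over 0.1 (0.105, 0.134 and 0.185), and there the pairing comes from the data alone. Normexp used the median spot signal, because the mean signal is not used here.

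The procedures were tested on simulated data. For the line comparison at 10 DAF, with 30217 probes, 32.8% of changes of 0.5 log2 units, 70.2% of changes of 1 and 86.6% of changes of 2 were recovered, and 4.51% of calls were false. For the 4 steps, over 25097 genes, a true odds ratio of 8.86 was found as 8.38. In the camera test of that line comparison, a list of 8 genes raised by 1 was called up, and 4% of 200 unchanged lists had a p under 0.05. The simulated noise was independent between genes and slides, and in the test of calls only 67 probes per size were changed. In the data far more probes were called, and list members had estimated correlations of up to 0.316. These rates therefore need not hold for the data.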

Results

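Gene expression was measured in the pericarp, the fleshy wall of the tomato fruit, in a pair of genotypes. M82 is a cultivated tomato, and IL8-3 is an introgression line that carries a segment of chromosome 8 of the wild relative Solanum pennellii in the M82 background. The labels give 4 stages for each line: 10, 20 and 30 days after flowering (DAF) and ripening, which the growth protocol equates with breaker, the stage at which fruit begins to colour. Each of the 8 groups had 3 arrays, described as biological replicates from fruit of 8 plants, so 24 arrays were compared. On each array, between 25472 and 30604 of the 43803 non-control probes were well above background (58.2% to 69.9%). The tests covered 30260 probes and 25134 genes with a locus tag. Neither the files nor the reference table pair these tags with gene names, so genes are described through 8 lists of loci, and at most 2 loci per direction are printed. The number of arrays, 3 per group, limits the precision of every comparison.

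The labels were checked with ripening gene lists, whose course is known, after the principal components, single ripening loci and chromosome 8 probes had been looked at and had shown the pattern. Ripening regulators (factors that control the onset of ripening), ethylene synthesis and response genes, and cell wall softening genes are known to be induced around breaker in tomato. On the arrays labelled M82, these lists stayed low at every labelled stage. The 8 ripening regulators deviated from their all-array means by -1.97 ± 0.13 log2 units (SD, n = 3) at 10 DAF, -2.08 ± 0.03 at 20 DAF, -1.70 ± 0.06 at 30 DAF and -1.74 ± 0.21 at ripening. On the arrays labelled IL8-3 the same mean deviation was 1.34 ± 0.09 at 10 DAF, 0.18 ± 0.04 at 20 DAF, 2.47 ± 0.04 at 30 DAF and 3.50 ± 0.06 at ripening. Cell wall softening genes, whose products loosen pectin and other wall polymers, deviated by -2.85 ± 0.29 on the arrays labelled M82 ripening and by 1.21 ± 0.14 on those labelled IL8-3 10 DAF. In each of these 3 lists, every array labelled IL8-3 lay above every array labelled M82; for the ripening regulators the lowest was 0.15 and the highest -1.61. Genes of chromosome 8, where the lines differ by descent, were not in excess among those that separated the labelled lines: 389 of 1805 were called the same way in all 4 line comparisons, 21.6% against 22.3% elsewhere (Fisher's exact test, two-sided, adjusted p = 0.599). Because both checks went against the labels, groups are named as arrays labelled with a line and a stage, and every direction given here is a direction between labels.

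**Figure D1:**
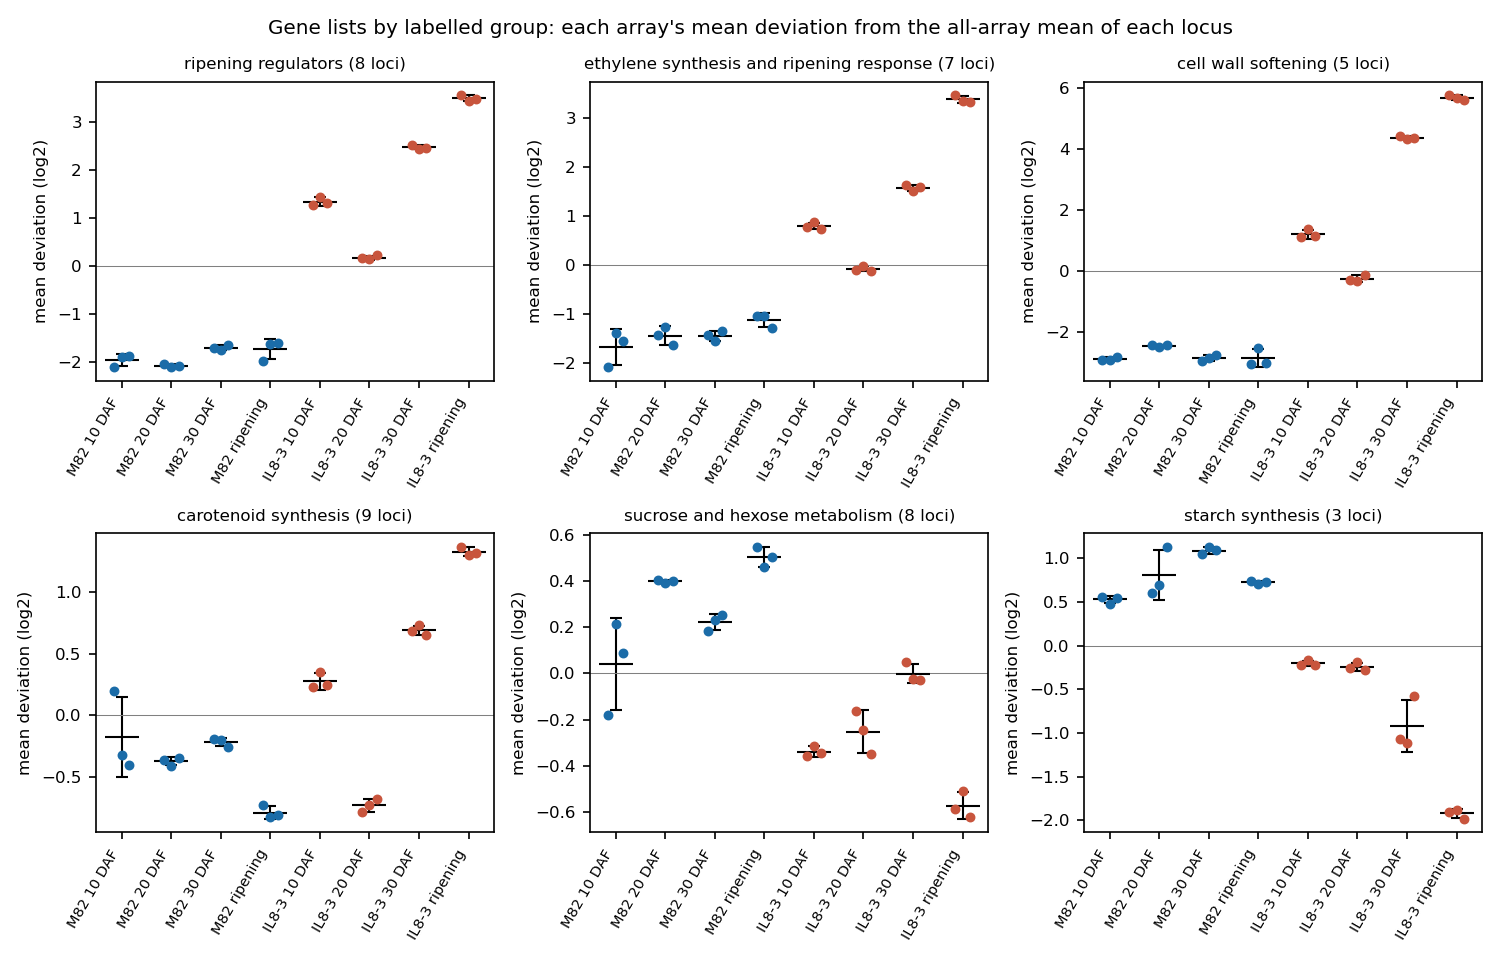
Mean deviation (log2 units, vertical axis) of 6 gene lists from the all-array mean of each locus, for each array (points) of the 8 labelled groups (horizontal axis), with the group mean and SD as bars (n = 3). Ripening regulators lay between -2.12 and -1.61 on all arrays labelled M82 and between 0.15 and 3.57 on those labelled IL8-3; 2 arrays labelled IL8-3 30 DAF and 1 labelled M82 20 DAF lack 1 of the 3 starch loci.

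The first principal component of the tested probes, with 53.6% of the variance, separated the labelled lines. Arrays labelled M82 scored from -140.3 to -99.1 on it and arrays labelled IL8-3 from 42.3 to 235.0. Components 2 and 3 held 16.5% and 9.74% of the variance. Arrays of one group differed from each other with an SD of 0.335 to 0.537 log2 units, except for the array labelled M82 10 DAF replicate 1. That array differed from replicates 2 and 3 of its group with an SD of 1.07 and 1.11, while these differed from each other with an SD of 0.462. Its correlation across probes, which are not independent replicates, was 0.949 and 0.945 with its own group and 0.963 to 0.966 with the arrays labelled M82 20 DAF.

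**Figure D2:**
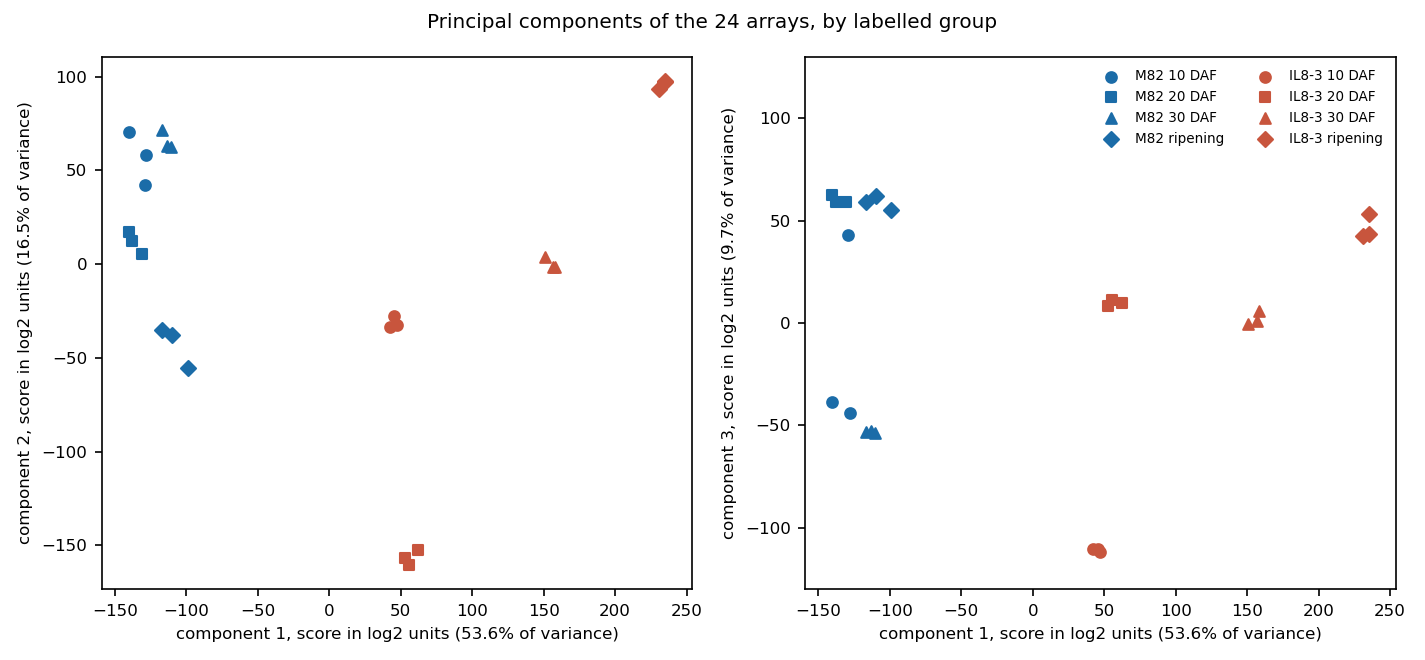
Scores of the 24 arrays (log2 units) on principal components 1 and 2 (left) and 1 and 3 (right), with 53.6%, 16.5% and 9.74% of the variance; colours mark the labelled line and symbols the labelled stage. Component 1 ranged from -140.3 to -99.1 on arrays labelled M82 and from 42.3 to 235.0 on arrays labelled IL8-3.

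The first question was how the fruit of the lines differed at each stage. At 10 DAF, ripening genes were higher on the arrays labelled IL8-3 than on those labelled M82. All 8 ripening regulators were higher, with a median log2 difference of 2.32 (camera, adjusted p = 2.49e-06; adjusted p = 0.00622 with an estimated correlation). Of 7 ethylene synthesis and response genes, 6 were higher and 1 was not called, with a median of 1.28 (adjusted p = 0.0026; adjusted p = 0.041 with an estimated correlation). Cell wall softening genes had a median of 3.48, with 4 higher and 1 lower (adjusted p = 0.00312; adjusted p = 0.0295 with an estimated correlation). Carotenoid synthesis genes, whose pathway includes the red pigments of ripe fruit, had 3 members higher, 2 lower and 4 not called. The list did not pass the camera test (median 0.30, adjusted p = 0.227). Among 8 sucrose and hexose metabolism genes, 3 were higher and 4 lower (median -0.23, adjusted p = 0.301), and of 3 starch synthesis genes 1 was higher and 2 were lower (median -0.89). In total 17651 probes were called, 9121 higher and 8530 lower, of which 3703 and 4175 differed by at least 2-fold; a fit of the compared groups alone called 9796. When arrays were centred on their medians, 65.4% of the calls were higher in place of 51.7%, and the median of all probes rose to 0.25. No slide held arrays of both labelled lines, so slide and line cannot be told apart in any of the line comparisons.

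At 20 DAF the ripening regulators and cell wall softening genes had smaller median differences than at 10 DAF. Ripening regulators were higher for 5 loci and lower for 1, with a median of 1.501 (adjusted p = 0.00985), a call lost with an estimated correlation (adjusted p = 0.136 with an estimated correlation). Cell wall softening genes (4 higher, 1 lower, median 1.15) and ethylene genes (4 higher, 1 lower, 2 not called, median 0.77) did not pass the list test (adjusted p = 0.144 for both). The ethylene median was 1.39 without a locus for which no fold could be bounded, being above background on 1 of the 6 arrays. Sucrose and hexose metabolism genes were lower for 6 of 8 loci, with a median of -1.15, and this list missed the threshold too (adjusted p = 0.112). Carotenoid genes had 2 higher and 5 lower members (median -0.51, adjusted p = 0.367). Starch synthesis genes had a median of -1.75, with 1 higher and 2 lower. Of 19501 probes called, 10330 were higher and 9171 lower, and 9705 differed by at least 2-fold. The median of all probes was 0.23 under median centring.

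The ripening lists stood far apart at 30 DAF. All 8 ripening regulators were higher on the arrays labelled IL8-3, with a median of 2.86 (adjusted p = 1.56e-05; adjusted p = 0.00566 with an estimated correlation). The 5 cell wall softening genes were also all higher, by a median of 5.70 (adjusted p = 2.68e-05; adjusted p = 0.00492 with an estimated correlation). Ethylene genes were higher for 5 loci and lower for 1 (median 2.53, adjusted p = 0.0043), and this call was lost with an estimated correlation (adjusted p = 0.061 with an estimated correlation). Carotenoid genes had 5 higher and 3 lower members (median 1.55, adjusted p = 0.121). For sucrose and hexose genes 2 were higher and 3 lower, and their median of -0.15 turned to 0.23 under median centring (adjusted p = 0.841). Of the starch synthesis genes 2 were lower; the other had only 1 usable array labelled IL8-3 30 DAF and is not counted. The test called 20681 probes, 9408 higher and 11273 lower, with 4477 and 6299 of at least 2-fold. Median centring raised the share of higher calls from 45.5% to 64.6% and the median of all probes to 0.29; that median was 0.08 with quantile normalization and 0.03 with normexp, against -0.09.

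The largest differences of the 4 stages, by number of calls, were those at ripening. Ripening regulators were higher at all 8 loci (median 4.11, adjusted p = 5.25e-05; adjusted p = 0.00862 with an estimated correlation), and the 5 cell wall softening genes were higher by a median of 5.93 (adjusted p = 0.000408; adjusted p = 0.00862 with an estimated correlation). Ethylene genes were higher for 6 of 7 loci, by a median of 4.05 (adjusted p = 0.000887; adjusted p = 0.0309 with an estimated correlation). Carotenoid genes were higher for 6 loci and lower for 2 (median 2.46, adjusted p = 0.0358). The carotenoid call was lost with an estimated correlation (adjusted p = 0.243 with an estimated correlation), with median centring (adjusted p = 0.115) and with quantile normalization (adjusted p = 0.0607). Of the sucrose and hexose genes, 3 were higher and 5 lower (median -1.23, adjusted p = 0.163), and starch synthesis genes had a median of -3.18 with 1 higher and 2 lower. Of 23736 probes called, 11815 were higher and 11921 lower, and 15087 differed by at least 2-fold. Under median centring 65.7% of the calls were higher in place of 49.8%, with a median of all probes of 0.57; quantile normalization gave 0.15.

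For the mean of the stages, single genes were picked from chromosome 8, the chromosome of the introgressed segment. On other chromosomes, 8 genes called the same way at all stages had a fitted mean difference at least as large as the smallest of those printed. By their tags Solyc08g005770 and Solyc08g007660 lie near the start of the chromosome, not in the windows with an excess described below. Their place on chromosome 8 alone therefore does not tie the differences to the segment. Solyc08g005770 and Solyc08g066240 were higher on the arrays labelled IL8-3 at all 4 stages. On these arrays the levels of both fell from 10 to 20 DAF and then rose up to ripening, as those of the ripening regulators did. Neither was well above background on any array labelled M82, so only bounds on their folds are given. For Solyc08g005770 these were at least 1179-fold at 10 DAF, at least 219.6-fold at 20 DAF, at least 6142-fold at 30 DAF and at least 14900-fold at ripening. For Solyc08g066240 they were at least 499.9-fold, at least 39.83-fold, at least 2908-fold and at least 9858-fold at the same stages. Solyc08g065780 and Solyc08g007660 were lower on the arrays labelled IL8-3 at all 4 stages, and well above background on all arrays labelled M82. At 10 DAF Solyc08g065780 was 536.9-fold lower; no fold is given for Solyc08g007660, which was above background on only 1 of 3 arrays labelled IL8-3. From 20 DAF on neither was above background on an array labelled IL8-3. The folds were then at least 1152-, 2251- and 978.1-fold for Solyc08g065780 and at least 320.7-, 456- and 227.9-fold for Solyc08g007660. The contrast called 24491 probes, 12542 higher and 11949 lower, with 9056 of at least 2-fold.

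Development was then followed within each labelled line. From 10 to 20 DAF on the arrays labelled M82, sucrose and hexose metabolism genes had the largest list shift relative to the test: 4 of 8 were higher and 4 not called, with a median of 0.52 (adjusted p = 0.1). Among ethylene genes 2 were higher and 1 lower (median 0.36, or 0.42 without the locus below background in both groups, adjusted p = 0.164). Ripening regulators (3 higher, 2 lower, median -0.03, adjusted p = 0.929), cell wall softening genes (1 higher, 4 not called, median -0.16, or -0.21 with bounds, adjusted p = 0.929) and carotenoid genes (1 higher, 1 lower, median -0.17, adjusted p = 0.568) did not pass either. The sign of the ripening regulator median turned with quantile normalization, median centring, normexp and the slide as a block (0.03). Adjusted over the list alone, the members called were 5 higher for sucrose and hexose genes, 3 higher and 1 lower for ethylene genes, and 1 lower for carotenoid genes. Starch synthesis genes had 1 member higher and 2 not called (median 0.19). The step called 9976 probes, 4891 higher and 5085 lower, with 2717 of at least 2-fold; median centring moved the share of higher calls from 49.0% to 70.2% and the median of all probes to 0.10. With the slide as a block 4067 probes were called. Without the array labelled M82 10 DAF replicate 1 the count rose to 16270.

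From 20 to 30 DAF on the arrays labelled M82, no list passed the test. Ripening regulators had 3 higher and 1 lower members (median 0.13, or 0.06 with bounds, adjusted p = 0.802), and cell wall softening genes 1 higher and 1 lower (median 0.30, adjusted p = 0.926). The sign of the cell wall median turned with quantile normalization, to -0.09, with bounds, to -0.04, and with the slide as a block or within the slide, to -0.06. Sucrose and hexose genes had 2 higher and 4 lower members (median -0.36, adjusted p = 0.802), ethylene genes 2 higher and 2 lower, or 3 and 2 adjusted over the list alone (median -0.09, or -0.51 with the slide as a block, adjusted p = 0.802), and carotenoid genes 2 higher and 2 lower (median -0.07, adjusted p = 0.819). For starch synthesis genes 1 was higher and 2 were not called (median 0.05). The 13838 probes called were 7608 higher and 6230 lower, with 4727 of at least 2-fold. With the slide as a block the count was 9596, and within the shared slide, 2 arrays against 2, it was 14587.

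Between 30 DAF and ripening on the arrays labelled M82, the ripening lists again did not rise together. Carotenoid genes were lower for 4 loci and not called for 5 (median -0.43, adjusted p = 0.34). Ripening regulators had 2 higher and 2 lower members (median 0.04, or -0.05 with bounds, adjusted p = 0.986), ethylene genes 3 higher and 2 lower (median 0.07, or 0.24 with bounds, adjusted p = 0.598), and cell wall softening genes 1 higher and 1 lower (median -0.12, or -0.20 with bounds and -0.45 with the slide as a block, adjusted p = 0.771). The signs of these last 3 medians turned with quantile normalization. Sucrose and hexose genes had 4 higher and 2 lower members (median 0.22, adjusted p = 0.598), and starch synthesis genes 1 of each (median -0.16). Calls numbered 15477, 7872 higher and 7605 lower, with 6094 of at least 2-fold. The slide block left 9392 calls.

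The arrays labelled IL8-3 showed a fall of carotenoid and cell wall genes from 10 to 20 DAF. Carotenoid genes were lower for 7 of 9 loci (median -1.10, adjusted p = 0.0026) and cell wall softening genes for 4 of 5 (median -2.18, adjusted p = 0.0407). Both calls were lost with an estimated correlation (adjusted p = 0.182 with an estimated correlation, for each). With the slide as a block these medians were -1.14 and -2.37. Ripening regulators were lower for 6 loci and higher for 2 (median -0.79, adjusted p = 0.183), ethylene genes lower for 4 and higher for 2 (median -0.67, adjusted p = 0.304), and sucrose and hexose genes higher for 2 and lower for 3 (median 0.08, adjusted p = 0.977). Starch synthesis genes had 1 member each way over all genes tested and 1 higher and 2 lower adjusted over the list alone (median -0.30). The step called 15012 probes, 7055 higher and 7957 lower, with 5948 of at least 2-fold, and the share of higher calls was 47.0%, or 57.5% under median centring, where the median of all probes was 0.06 against -0.05. The slide block left 9304 calls.

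The ripening lists rose together from 20 to 30 DAF on the arrays labelled IL8-3. All 5 cell wall softening genes were higher, by a median of 6.14 (adjusted p = 0.000132; adjusted p = 0.00721 with an estimated correlation), and 7 of 8 ripening regulators were higher with 1 lower (median 1.87, adjusted p = 0.00069; adjusted p = 0.0302 with an estimated correlation). Carotenoid genes were higher for 7 of 9 loci (median 1.19, adjusted p = 0.000897) and ethylene genes for 5 of 7, with 2 lower (median 2.24, adjusted p = 0.0171). These last calls were lost with an estimated correlation (adjusted p = 0.101 with an estimated correlation, for each). Within the shared slide, 2 arrays against 2, the medians were 6.08 for cell wall, 1.86 for ripening regulator, 1.18 for carotenoid and 2.20 for ethylene genes, and the slide block gave the same values. Sucrose and hexose genes had 4 higher and 3 lower members (median 0.33, adjusted p = 0.478), and starch synthesis genes 1 of each, beside 1 with a single usable array at 30 DAF. Of 18408 calls, 8795 were higher and 9613 lower, with 8611 of at least 2-fold. The count was 15393 with the slide as a block and 17699 within the slide, and the median of all probes was 0.11 under median centring.

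From 30 DAF to ripening on the arrays labelled IL8-3, ethylene genes and ripening regulators rose further. Ethylene genes were higher for 6 of 7 loci (median 1.77, adjusted p = 0.0222) and ripening regulators for 5 of 8, with 3 not called (median 1.18, adjusted p = 0.025). Both calls were lost with an estimated correlation (adjusted p = 0.104 with an estimated correlation, for each), and that of the regulators also with quantile normalization (adjusted p = 0.0933). With the slide as a block the medians were 1.78 and 1.16. Cell wall softening genes (4 higher, 1 lower, median 1.60, adjusted p = 0.0609), carotenoid genes (7 higher, 2 lower, median 0.82, adjusted p = 0.068) and sucrose and hexose genes (1 higher, 5 lower, median -0.42, adjusted p = 0.0609) missed the threshold. Of the starch synthesis genes 2 were lower, and the other, with 1 usable array at 30 DAF, is not counted. There were 19063 calls, 10787 higher and 8276 lower, with 8568 of at least 2-fold, and the median of all probes was 0.15 (0.33 under median centring). The slide block left 14253 calls.

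Whether a developmental step differed between the labelled lines was tested as an interaction. From 10 to 20 DAF, the step was lower on the arrays labelled IL8-3 than on those labelled M82 for 7 of 9 carotenoid genes, with 1 higher, and for 5 of 8 ripening regulators, with 2 higher (median differences of the steps -0.93 and -1.28). From 20 to 30 DAF, the step was higher on the arrays labelled IL8-3 for all 5 cell wall softening genes (median 5.36), 7 of 8 ripening regulators with 1 lower (median 1.84), 5 of 7 ethylene genes with 2 lower (median 2.68) and 6 of 9 carotenoid genes with 2 lower (median 1.27). Between 30 DAF and ripening it was higher for 7 of 9 carotenoid genes with 1 lower (median 0.91) and 4 of 5 cell wall softening genes with 1 lower (median 2.02), and lower for 5 of 8 sucrose and hexose genes with 1 higher (median -1.002). In that interval 3 ripening regulators were higher and 5 not called (median 0.15), and of the ethylene genes 3 were higher, 1 lower and 3 not called (median 0.83). Interactions were called for 9525 probes (4611 higher, 4914 lower), 16486 probes (7106 higher, 9380 lower) and 18544 probes (9890 higher, 8654 lower) over the 3 intervals in turn. With the slide as a block they numbered 4154, 12659 and 13348. Without the array labelled M82 10 DAF replicate 1, and with no block, the first interval had 14320.

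The share of line calls among genes of chromosome 8 did not pass the test for a difference from genes elsewhere at any stage. Called genes were 59.3% of those on chromosome 8 and 59.2% of the others at 10 DAF (odds ratio 1.01, Fisher's exact test, adjusted p = 0.901), 66.3% and 64.7% at 20 DAF (1.07, adjusted p = 0.549), 70.3% and 69.6% at 30 DAF (1.03, adjusted p = 0.62) and 77.0% and 79.3% at ripening (0.874, adjusted p = 0.268). Among falls alone at 20 DAF it did pass (1.15, adjusted p = 0.0451), and chromosome 11 had fewer line calls than the rest at 10 DAF (0.852, adjusted p = 0.0178). In 4 of the 6 steps within a labelled line they were more often called than genes elsewhere. The odds ratios were 1.39 (adjusted p = 5.72e-10), 1.25 (adjusted p = 4.79e-05) and 1.17 (adjusted p = 0.0192) for the successive steps on the arrays labelled M82, and 1.18 (adjusted p = 0.00811), 1.097 (adjusted p = 0.211) and 1.06 (adjusted p = 0.411) on those labelled IL8-3. Smaller excesses were found for chromosome 6 (1.175, adjusted p = 0.00291) and chromosome 4 (1.134, adjusted p = 0.0299) in the first and second step on the arrays labelled M82. Chromosome 12 had fewer calls than the rest in all 3 of those steps (0.803, adjusted p = 0.000277; 0.825, adjusted p = 0.000822; 0.870, adjusted p = 0.0214), and deficits of chromosomes 9, 10 or 11 also passed in some steps. After these results were seen, 4 steps that share no arrays were compared: 20 against 10 DAF and ripening against 30 DAF in each labelled line. On chromosome 8, 180 of 1805 genes were called the same way in all 4, 9.97% against 3.89% elsewhere (odds ratio 2.73, Fisher's exact test, adjusted p = 2.15e-25), and chromosome 11 had fewer than the rest (odds ratio 0.631, adjusted p = 0.006).

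These genes lay at one end of the chromosome, in the order of their locus tags. From window 28 of the 36 windows of 50 genes to the end of the chromosome, including the few genes left after the last window, 119 of 455 genes were called the same way in the 4 steps. This was 26.2% against 3.93% of all other genes (odds ratio 8.66, Fisher's exact test, p = 2.66e-59 for windows chosen from the same data). Of the 119, 37 were higher and 82 lower at the later stage of each step. The rest of chromosome 8 held 61 such genes among 1350 (odds ratio 1.17 against the other chromosomes, Fisher's exact test, p = 0.249). Without the array labelled M82 10 DAF replicate 1, the odds ratio of the whole chromosome was 1.81. Of the 455 genes, 139 were then called the same way, while the step from 10 to 20 DAF on the arrays labelled M82 had 16270 calls.

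**Figure D3:**
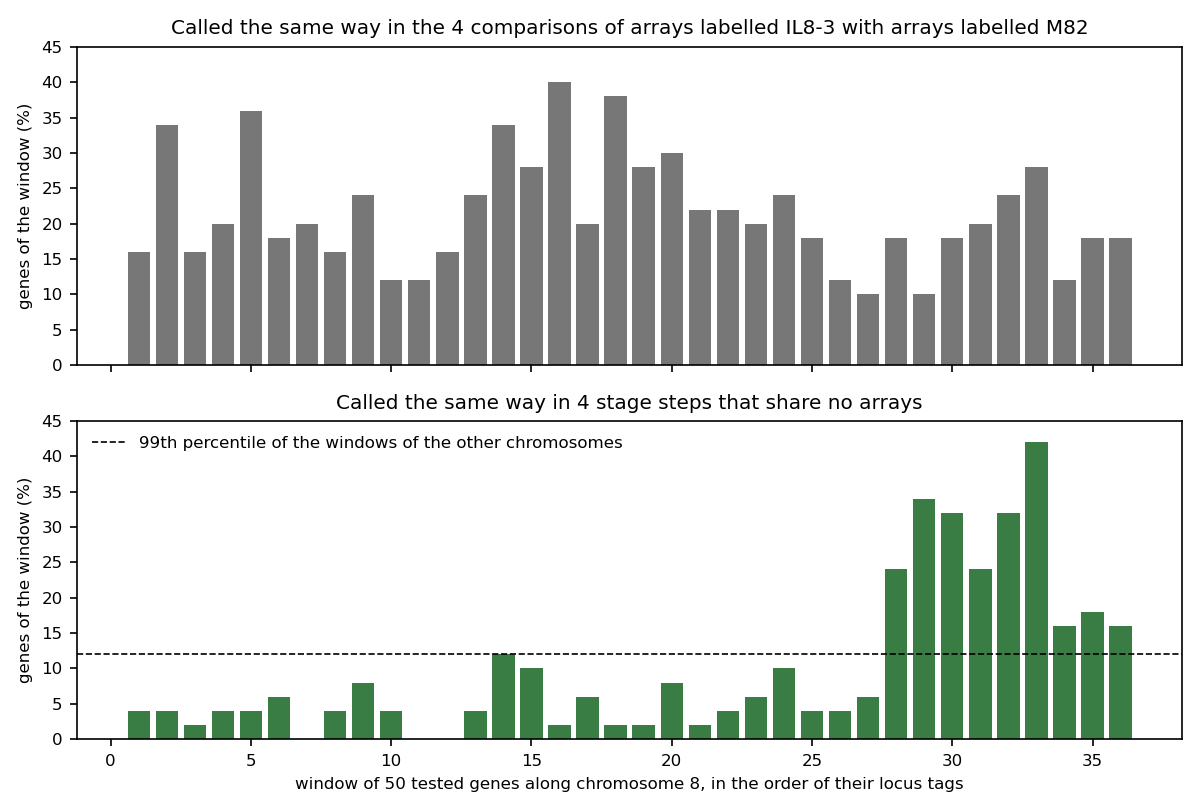
Percent of genes (vertical axis) in each window of 50 tested genes along chromosome 8 (horizontal axis, in the order of locus tags) that were called the same way in the 4 line comparisons (top) and in 4 steps that share no arrays (bottom); the dashed line is the 99th percentile of windows on the other chromosomes, 12%. In the bottom panel windows 28 to 36 reached 16% to 42%, and the highest window of another chromosome reached 24%.

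Line effects were correlated between successive stages. Across 30260 probes, which are not independent replicates, the log2 differences between the labelled lines had a Pearson r of 0.773 between 10 and 20 DAF, 0.632 between 20 and 30 DAF and 0.652 between 30 DAF and ripening, and 77.0%, 67.8% and 69.4% of probes had the same sign. The stages compared share no arrays, but successive stages share a slide within each labelled line, and no slide holds both lines. A slide effect common to both stages therefore cannot be told apart from these correlations. The steps of the labelled lines had an r of 0.461 from 10 to 20 DAF, 0.245 from 20 to 30 DAF and -0.0934 from 30 DAF to ripening.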

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

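The results in this part come from planned tests, except for the description of the splits that exchange a stage, which was made after they were seen. Steps of development differed between the labelled lines by the interaction test for 9525 probes from 10 to 20 DAF, 16486 from 20 to 30 DAF and 18544 from 30 DAF to ripening. Among the chromosome 8 genes printed by ID, the step of Solyc08g005770 on the arrays labelled IL8-3 minus that on the arrays labelled M82 was -2.40, 4.13 and 1.30 log2 units over the 3 intervals. For Solyc08g066240 it was -3.60, 5.94 and 1.97, and for Solyc08g065780 -2.22, -1.81 and 2.10. These are no measured sizes: the former 2 were below background on all arrays labelled M82, and the latter on those labelled IL8-3 from 20 DAF on, so part of each value is a difference between floor signals. No such difference was called for Solyc08g007660 (adjusted p = 0.221, 0.599 and 0.233). Because the label checks went against the labels, these are differences between labels.

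Other splits of the arrays were counted over the 30217 probes without a missing value. For the mean of the line comparisons, 1 of 100 splits, the real one, gave as many calls (24455, highest other 9782). A chance division of the arrays can therefore be excluded. A difference between slides cannot, since no slide held arrays of both labelled lines. For the interactions, 11 of 100 splits gave as many calls from 10 to 20 DAF (real 9513, highest other 21463), so chance cannot be excluded there. For the later intervals it was 2 of 100 (16466, highest other 22113) and 4 of 100 (18513, highest other 23823), shares under 0.05. These splits exchange lines within a stage, so they are no clean measure of chance for an interaction, and chance is not called excluded for any interval. Of the 10, 1 and 3 other splits with as many calls, 6, 1 and 2 exchanged the lines of a whole stage, as did the highest of each interval. The highest counts point to a structure of the samples, the large difference between the labelled lines, which such an exchange turns into an interaction. Without a whole stage exchanged the highest counts were 15925, 14890 and 18684, of which the first and the last exceed the real count.

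Comparisons of 3 arrays with 3 allow 10 splits, too few for a share under 0.05. The real count and the highest other were 17628 and 3855 for the lines at 10 DAF, 19471 and 0 at 20 DAF, 20652 and 0 at 30 DAF, and 23698 and 1 at ripening. They were 9966 and 7293, 13814 and 0, and 15460 and 1 for the successive steps on the arrays labelled M82. On the arrays labelled IL8-3 they were 14990 and 11, 18385 and 2, and 19036 and 10. For the first of these, all 3 same-number correlations were over 0.1, though the labels give no pairing. There the 3 other splits that part all same-number pairs gave at most 0 calls by limma, and the 11 came from a split that parts fewer.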

How the results depend on the processing

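All alternatives here were planned, except the fits within a slide and the odds ratios of genes called the same way. No direction of a called list test, single gene or chromosome 8 odds ratio was reversed. For counts of calls only the totals were compared, and the side with more calls turned in some comparisons. For the lines at 30 DAF the share of higher calls was 45.5%, against 53.2% with quantile normalization, 64.6% with median centring and 53.4% with normexp. For 30 against 20 DAF on the arrays labelled M82 it was 54.98%, against 45.85% with median centring. Among counts of calls, 268 values stayed within 1.5 times the reported one and 11 did not, in 5 of the 14 comparisons. Fitting only the groups compared gave 9796 calls for the lines at 10 DAF, 1856 for 20 against 10 DAF on the arrays labelled M82 and 6346 for the interaction from 10 to 20 DAF; fewer arrays enter that fit. The slide block gave 4067 for that M82 step, 9392 for ripening against 30 DAF on the same labels, 9304 for 20 against 10 DAF on the arrays labelled IL8-3 and 4154 for the first interaction, where each step rests on fewer arrays of one slide. That M82 step had 15652 calls with array weights and 0 within its slide by limma (1901 at an unadjusted p under 0.05), where 1 array stood against 3 that include the one apart, so few calls were to be had. Leaving out each array gave it 7950 to 16270 calls and the first interaction 8365 to 14320; the highest values were those without the array labelled M82 10 DAF replicate 1.

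For falls alone at 20 DAF, chromosome 8 had an odds ratio of 1.15 (adjusted p = 0.0451); the other 92 values of these shares kept their side of the threshold. The correlation of line effects between 20 and 30 DAF was 0.585 with normexp, 0.611 with no filter and 0.557 with probes well above background on all arrays, and that between 30 DAF and ripening 0.623 and 0.59 with the last 2. The cause was not tested for these. Of the list tests 794 kept their side of the threshold, 12 lost a call, each given beside its result, and 14 gained one. From 30 DAF to ripening on the arrays labelled IL8-3, 4 alternatives called the sucrose and hexose list (adjusted p = 0.0183 to 0.0484), 3 the cell wall list (0.0302 to 0.045) and 2 the carotenoid list (0.0323 and 0.0389). From 10 to 20 DAF, normexp called the ripening regulators on those labels (0.0485); on the arrays labelled M82 leaving out replicate 2 at 10 DAF called the ethylene and the sucrose and hexose lists (0.0398 each), and no filter called the latter (0.0282). Without M82 10 DAF replicate 1 the carotenoid list was called between the lines at 10 DAF (0.0398). All 388 values of single genes and 65 odds ratios of genes called the same way kept theirs.

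The replicate numbers did not pair the samples by their correlations, apart from a weak sign of it for 20 against 10 DAF on the arrays labelled IL8-3. Over all groups same-numbered arrays had correlations of -0.412 to 0.278, with 14 of 84 over 0.1, and 7 of 24 arrays correlated best with their own number. The replicate block gave 17534, 19390, 20512 and 23680 calls for the lines at the 4 stages and 14820 for that step; it moved no count by over 1.5 times and changed no call of a list. Slides as a fixed block could not be fitted for the line comparisons, and the planned change of list membership was not run, since only loci could be used. Signal over background limits the dim genes, for which folds are bounds.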

Other observations

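The tests of the mislabelling, of the lines with the labels as given, of the genes called higher in the distal block and of the single array were chosen only after the results were seen; the slide block and the comparison of probes of one gene were set before theirs. The lists too small to test had these values. Of 2 chloroplast regulators, which promote chloroplast development in green fruit, 1 was well above background on all arrays. It was higher on the arrays labelled IL8-3 at 10 DAF (1.31 log2 units), 30 DAF (1.38) and ripening (4.63) and lower at 20 DAF (-0.54), and from 30 DAF to ripening it fell on the arrays labelled M82 (-0.87) and rose on those labelled IL8-3 (2.39). The other was above background on at most 1 of 3 arrays of each group labelled M82; at ripening it was at least 16.7-fold higher on the arrays labelled IL8-3. Of 3 loci of GABA and amino acid metabolism, 1 was higher and 2 were lower on the arrays labelled IL8-3 at every stage, with medians of -0.65, -0.98, -2.50 and -2.98; at 10 DAF their mean was 0.29, of the opposite sign. Median, mean and test also differed in sign for ripening regulators (-0.03, -0.11, test upward) and cell wall genes (-0.16, 0.43, upward) from 10 to 20 DAF on the arrays labelled M82. The same held there for cell wall genes (0.30, -0.40, downward) and carotenoid genes (-0.07, 0.15, upward) from 20 to 30 DAF, and for ripening regulators (0.04, -0.04, upward) from 30 DAF to ripening.

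Neither ripening genes nor the distal genes of chromosome 8 followed the labels. A difference between the lines as labelled needs an excess of chromosome 8 among genes called the same way in the 4 line comparisons. The odds ratio there was 0.960. For the distal genes, the odds ratio in the 4 steps with the slide as a block, 5.09, argues against a difference between slides. It cannot speak to the gap in ripening genes between the labelled lines, because no slide held arrays of both. A candidate explanation is that labels of line and stage were exchanged between groups of arrays. It asked for an odds ratio above 2 in the 4 steps within the labelled lines. This was 2.73, but 1.81 without the array labelled M82 10 DAF replicate 1. Without that array the distal genes called the same way numbered 139, against 119 with it, so the lower ratio came with no loss of them. The pattern of the distal genes led to the idea, so the test does not decide it. A change of the distal genes with stage in both lines would have to turn back at 30 DAF and again at ripening. On all arrays labelled 10 or 30 DAF the 139 genes had mean deviations of 1.184 to 1.337, positive towards the earlier stage of a step. They were -1.631 to -0.499 on those labelled 20 DAF or ripening. The genes were picked for the steps to 20 DAF and to ripening. That choice favours values towards the later side at 20 DAF and towards the earlier side at 30 DAF. The return at 30 DAF is therefore not independent of the choice. A change with stage stays open too, and no array was given another label here.

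In the distal block of chromosome 8, 119 genes changed the same way in 4 steps. Wild-relative sequence under probes designed on cultivated tomato could lower a signal on one side. The first form of the test was also chosen after results were seen. It asked for a share of genes higher under 10 percent, against over 25 percent otherwise. The share was 31.1% (exact interval 22.9% to 40.2%), and 23.5% among genes of at least 2-fold, which decides neither. A second form, added after that result, gave an odds ratio of 3.86 for the block among genes called higher in all 4 steps, but it is no evidence, because the windows had been picked for such genes. Mismatch and a change of expression cannot be told apart for the 82 lower genes either, because only 2 of them had several tested probes, 50% of which differed by over 1 log2 unit. A difference in expression between the parental alleles is a hypothesis that stays open, untested.

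The array labelled M82 10 DAF replicate 1 stood apart from its group, with 3896 probes over 2-fold lower and 3640 over 2-fold higher than the mean of replicates 2 and 3. A loss of signal is argued against, since 11 of the 23 other arrays had fewer probes well above background; its median intensity (52.5) and spike-in slope (1.03) were the highest and its weight (0.0253) the lowest of all arrays, so another fault of the array stays open. An exchange with an array labelled M82 20 DAF is argued against by its mean deviation over 139 distal genes chosen without it, 1.18, against 1.32 and 1.31 for its own group and -0.74 to -0.50 for the arrays labelled M82 20 DAF. Other values lay nearer to the arrays labelled M82 20 DAF. The array scored 42.8 on principal component 3, against -44.1 and -38.5 for its own group and 59.2 to 62.4 for those arrays. Its correlation was higher with them (0.963 to 0.966) than with its group (0.949 and 0.945). An exchange would also have placed an array of its group among those labelled M82 20 DAF. The arrays with that label correlated with each other at 0.992 to 0.994, so none of them stood apart. A wrong label of another kind or a difference between the fruit sampled may also remain, and no biological explanation was tested.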
